A study of Mus musculus with 40 samples.

How the data were processed

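Decidual tissue from mice on gestation day 8.5 was profiled by RNA sequencing in 40 libraries. Per the labels' protocols, poly(A) libraries were made with a TruSeq mRNA kit and sequenced paired-end on a NovaSeq instrument. The submitters' processing notes name FastQC, HISAT2 2.0.3, featureCounts, edgeR and the GRCm38.p5 build, without saying which step each served. The annotation release, the strand setting, the treatment of reads that map to several places and any filter are not given in the sources used here. The authors deposited 1 table of raw gene counts for the whole series, whole numbers of reads per gene with no normalization per the file headers and the values, with 55385 genes identified by versioned Ensembl IDs.

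Total counts ran from 14672405 to 24686314 per library (median 19401491). They measure depth after assignment to genes, and counting error sets a limit for genes at a few CPM or less. All 37 genes of the mitochondrial genome were at 0 in every library, so mitochondrial RNA could not be used as a sign of RNA quality. With them, 18713 genes had 0 counts in every library. Symbols were taken by Ensembl ID without its version, which matched 55144 IDs (99.6%), and the unmatched IDs held 0.00197% of all counts. For the 107 symbols on more than 1 ID, a list used the ID with the most counts. Coordinates are those of the GENCODE M21 annotation on GRCm38.

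Libraries were assigned to 8 groups of 5 from their titles (control or cKO, sex, compartment and replicate number). The genotype field of the labels follows sex and contradicts the titles on control and cKO, and was not used. A chi-square test over genes between replicates gave 4.27 to 464 per degree of freedom, above sampling noise, so each library was counted once. Some replicates lay close and may not be independent, as control male mesometrial 1 and 3 (4.60) and 4 and 5 (4.27, against 24.8 to 35.2 across). Whether replicate numbers mark pairs was checked on deviations of log2 CPM from group means over 11061 genes with a mean of at least 5 CPM. Every pair of same-numbered libraries correlated above 0.1 between the cKO groups (0.211 to 0.864) and between the female control groups of both compartments (0.235 to 0.64). Same-numbered libraries did not do so between cKO and control groups or between the male control groups, where replicate 2 gave -0.843. No label says what a shared number marks, so cKO pairing rests on this correlation alone.

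Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), with TMM scaling, the filterByExpr filter on the groups, 1 coefficient per group and no replicate block, and called at a Benjamini-Hochberg adjusted p under 0.05. The 20 libraries of a compartment were fitted together for the cKO comparisons, their male minus female difference and the male against female comparisons (16804 mesometrial and 15705 anti-mesometrial genes tested). All 40 libraries were fitted together for the compartment comparison and for the difference of the cKO effect between compartments (17495 genes). Standard errors are the absolute log2 fold change divided by the square root of F. CPM means and SDs were computed from TMM-scaled library sizes of the fit, except where total counts are stated. A fold change of a gene with a group at or near 0 counts depends on the prior count and is not given as a bound. Foxa2, Ltf, Lif and the summed Y-linked genes were compared by 2-sided exact permutation tests of their CPM (scipy 1.17.1), which allow no p below 0.00794 for 5 against 5.

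The 31 gene lists, which cover decidual, gland, vascular, immune, placental and embryonic cell types, pathways and signs of tissue handling, were written from general knowledge. Each list with at least 3 tested genes was tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the lists within a comparison. Beside it stand the counts of members past the threshold over all genes and adjusted over the list alone, and the p with an estimated correlation. In simulated data with the ribosomal list raised, camera called that list in each of 8 comparisons and at most 1 other list, but these data hold no genes that vary together between samples. The named genes are Foxa2, Ltf and Lif, and the 8 largest rises and 8 largest falls of each cKO comparison (5 and 5 for other comparisons) among called genes with an average log2 CPM of at least 1. Predicted, Riken and pseudogene symbols were left out. Up to 4 members of each described list with the smallest adjusted p, and up to 10 genes per direction shared by comparisons, were added. The lists to describe were chosen after list results had been seen. The groups, tests, gene lists, rule for named genes and alternatives were set before the data were examined, with the exceptions named here and in the closing section.

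The tests were tried on simulated counts drawn from the real means and library sizes, with 200 genes changed. A change of 1 on the log2 scale was recovered for 88% of genes in male mesometrial and 80% in male anti-mesometrial cKO against control, and a change of 2 for 97% in each. For the compartment comparison the shares were 89% and 99%, and for the difference of the cKO effect between compartments 74% and 97%. The alternatives were RLE size factors, no low-count filter, DESeq2 1.42.0, a replicate block, a fit of only the 2 groups compared, each library left out in turn, camera with an estimated correlation, fry, and TMM-scaled sizes for Y-linked counts. Leaving out both control male replicate 2 libraries, leaving out cKO replicates 4 and 5, a block in the fit of 2 groups, a block for the lists, single libraries left out for Y-linked counts and lists, and splits that keep same-numbered libraries of both compartments together were chosen after seeing the data. Other splits of the libraries were drawn up to 100 times (60 for fits of 40 libraries), and transcripts of 2 pseudogenes were matched to the GENCODE transcripts with BLAST+ 2.17.0. All libraries of the count table were used.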

Results

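RNA was sequenced from mouse decidua, the uterine stroma transformed around an implanted embryo, on gestation day 8.5. Each decidua was divided into a mesometrial part, on the side of the uterus where the vessels enter and the placenta forms, and an anti-mesometrial part on the opposite side. Dams carried floxed Foxa2 alleles alone (control) or together with an iCre gene in the Ltf locus that deletes Foxa2 in the uterus (cKO). FOXA2 is a forkhead transcription factor of the uterine gland epithelium. Per the labels' protocols the cKO dams received injections of recombinant LIF, a cytokine that glands secrete for implantation. No such injection is described for controls, so deletion and LIF treatment were not separable. Sires were wild-type CD-1 males, and the sex in the labels was read as that of the conceptus, because every dam is female. The 40 libraries fell into 8 groups of 5, control or cKO, female or male, mesometrial or anti-mesometrial. Total counts ran from 14672405 to 24686314 per library, with a median of 19401491. No label names the dam or says that replicates came from separate dams, so p-values measure the spread between these samples, which may be technical. CPM below are on TMM-scaled library sizes, except those of Foxa2, Ltf, Lif and Y-linked genes by stratum and of single libraries, which are on total counts.

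Foxa2 (chromosome 2, 148042877 to 148046969, GRCm38, a protein-coding gene) was lower in the control mesometrial than in the control anti-mesometrial part, at 0.296 ± 0.578 against 2.01 ± 0.854 CPM (mean ± SD, n = 10 each, adjusted p = 1.17e-04, edgeR). The mesometrial mean was 0.117 CPM without the library labelled control male mesometrial replicate 2. In anti-mesometrial decidua with female conceptuses Foxa2 stood at 1.47 ± 0.966 CPM in cKO and 2.06 ± 0.279 CPM in control (SD, n = 5, 2-sided exact permutation p = 0.302). The cKO replicates 4 and 5 held 0.667 and 0.223 CPM and replicates 1 to 3 1.94 to 2.39 CPM, with controls from 1.75 to 2.45 CPM. With male conceptuses it stood at 1.70 ± 0.600 CPM in cKO and 1.13 ± 0.582 CPM in control (SD, n = 5, exact permutation p = 0.183). In mesometrial decidua Foxa2 lay at 0.178 ± 0.181 against 0.205 ± 0.148 CPM with female conceptuses and at 0.178 ± 0.234 against 0.401 ± 0.786 CPM with male conceptuses (cKO against control, SD, n = 5, exact permutation p = 0.746 and 0.802). The control male mean includes 1.80 CPM in replicate 2, without which it was 0.0504 ± 0.0706 CPM (SD, n = 4, exact permutation p = 0.492), so the direction rests on that library. Whole-gene counts do not tell deleted from undeleted exons, so these low values do not check the cKO labels. Ltf passed the exact permutation test at 0.05 in no cKO comparison (p = 0.183, 0.151, 0.754 and 0.841 in female and male mesometrial and female and male anti-mesometrial decidua). Lif lay at 1.38 ± 0.582 CPM in cKO and 2.86 ± 1.13 CPM in control female mesometrial decidua (SD, n = 5, exact permutation p = 0.0476, 0.19 after Benjamini-Hochberg adjustment over the 4 comparisons). The summed Y-linked genes were higher in male-labelled than in female-labelled groups in both compartments and both genotypes. Control means were 3.37 against 0.0227 CPM in mesometrial and 2.38 against 0 CPM in anti-mesometrial decidua, and cKO means were 6.96 against 0.0209 CPM and 6.81 against 0.0201 CPM (n = 5, exact permutation p = 0.00794 each, the smallest that 5 against 5 allows, and 0.00794 after adjustment over the 4 tests). No female-labelled library held more than 1 Y-linked count, and each male-labelled library held at least 5. Groups follow the titles, as the genotype field follows sex.

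**Figure D1:**
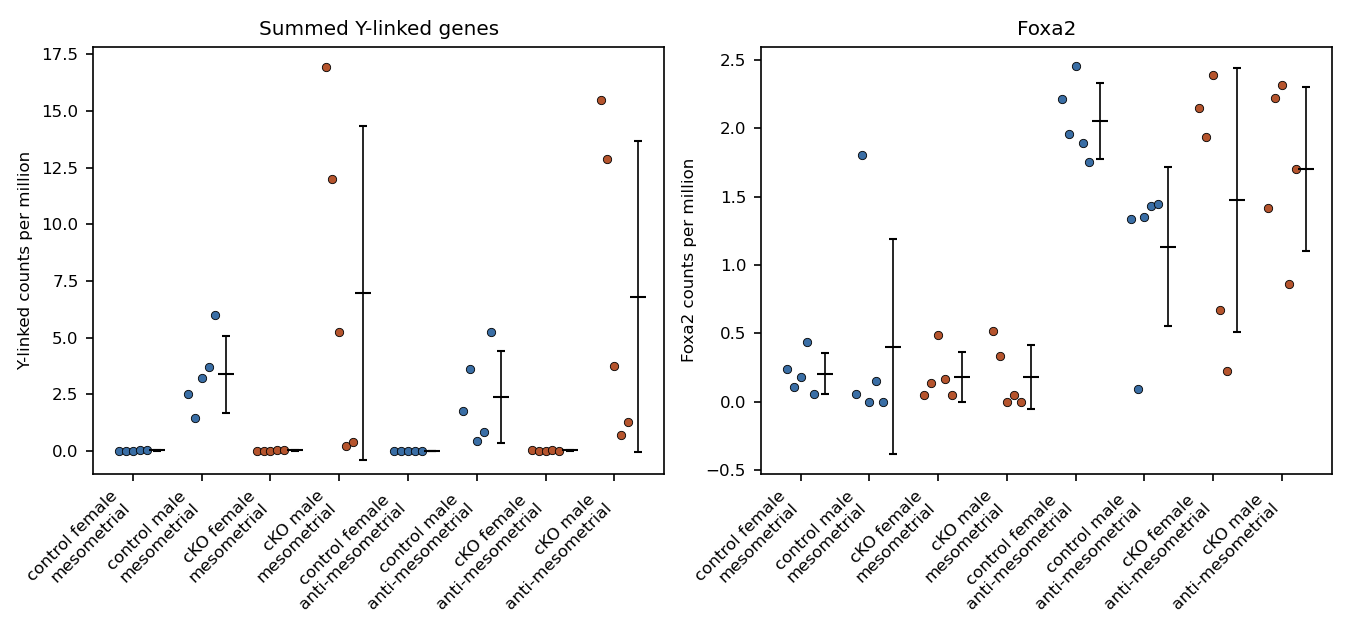
Summed Y-linked CPM (left) and Foxa2 CPM (right) in each of the 40 libraries, by group, with control in blue and cKO in red. Points are libraries, and the bar beside each group is the mean with its SD (n = 5). Foxa2 in cKO overlaps control in every stratum.

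The control groups gave the difference between the 2 sides of the decidua. Natural killer cell genes, cell cycle genes, interferon-response genes, glycolysis genes and fibrillar collagens were higher mesometrially, and prolactin-family hormones of the decidua and endoplasmic reticulum (ER) folding genes were higher anti-mesometrially. Each of these 7 list calls had adjusted p = 0.599 with an estimated correlation. The prolactin-family call was lost without cKO replicates 4 and 5 (camera adjusted p = 0.0517). It was also lost without control female mesometrial replicate 5 (0.0511) or control male anti-mesometrial replicate 2 (0.0734) or 3 (0.0582). Of 17495 genes tested, 6080 were higher and 5121 lower in mesometrial decidua, 4182 of them by at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 10 libraries against 10). Of the named genes, the largest mesometrial rises belonged to Adgra1, an adhesion G protein-coupled receptor (49.9 ± 10.8 against 6.35 ± 19.03 CPM, adjusted p = 1.15e-06). Others were the neural adhesion genes Chl1 (31.5 ± 7.67 against 3.99 ± 12.1 CPM) and Ntm (4.71 ± 1.33 against 0.414 ± 1.13 CPM), Hgf, hepatocyte growth factor (28.8 ± 4.22 against 3.45 ± 9.86 CPM), and the guidance factor Sema3d (6.05 ± 2.23 against 0.513 ± 1.42 CPM). The largest falls belonged to Elovl3, a fatty acid elongase (0.333 ± 1.01 against 6.08 ± 2.60 CPM, adjusted p = 3.85e-07) and to the neuropeptide precursor gene Pnoc (0.536 ± 1.44 against 7.76 ± 3.49 CPM). They were followed by the tryptase gene Tpsb2 (0.0853 ± 0.0964 against 2.70 ± 2.20 CPM), H2-M1, a class I histocompatibility gene (2.14 ± 5.68 against 35.1 ± 16.0 CPM), and Kng1, which encodes kininogen (2.15 ± 5.11 against 37.2 ± 16.9 CPM; mean ± SD, mesometrial first, n = 10). These means include the 2 libraries labelled control male replicate 2, which went against their compartment labels. Without them the anti-mesometrial means were 0.339, 0.169, 0.0573, 0.334 and 0.0666 CPM for Adgra1, Chl1, Ntm, Hgf and Sema3d. The mesometrial means were 0.0147, 0.083, 0.349 and 0.548 CPM for Elovl3, Pnoc, H2-M1 and Kng1.

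Among uterine natural killer cell genes, 24 of 27 tested rose mesometrially and 0 fell, with a median log2 fold change of 3.27 (camera adjusted p = 9.15e-07, and a median of 5.55 without control male anti-mesometrial replicate 2). The activating receptor gene Klrk1 stood at 4.53 ± 1.94 against 0.743 ± 1.23 CPM, the protease gene Ctsw at 13.7 ± 3.58 against 2.47 ± 6.43 CPM and the death ligand gene Fasl at 8.26 ± 2.21 against 1.33 ± 3.20 CPM. All 24 cell cycle genes rose, among them the proliferation marker Mki67 (126 ± 22.3 against 47.9 ± 21.4 CPM) and the kinesin Cenpe (30.2 ± 6.71 against 14.6 ± 4.50 CPM), with a list median of 0.91 (camera adjusted p = 1.36e-10). Of 24 interferon-response genes 22 rose and 0 fell, including Stat2 (84.1 ± 8.59 against 32.1 ± 22.3 CPM) and the antiviral synthetase Oas2 (29.3 ± 3.49 against 7.98 ± 8.70 CPM; camera adjusted p = 2.32e-09). Of 24 glycolysis and hypoxia genes 21 rose and 1 fell, including Tpi1 (380.5 ± 61.4 against 169 ± 97.3 CPM) and Eno1 (468 ± 74.4 against 210.0 ± 139 CPM; camera adjusted p = 9.57e-06). Of 20 fibrillar collagen and matrix genes 16 rose and 3 fell (camera adjusted p = 0.00172). Col3a1 (642 ± 219.5 against 127 ± 189 CPM) and Col1a2 (676 ± 259.8 against 137 ± 217 CPM) rose, whereas the matrix genes Postn (157 ± 141 against 737 ± 225 CPM) and Lox (132 ± 56.3 against 389.5 ± 124 CPM) fell. Without that library the anti-mesometrial means were 0.364, 0.4405 and 0.326 CPM for Klrk1, Ctsw and Fasl, 5.32 CPM for Oas2, and 67.7 and 68.6 CPM for Col3a1 and Col1a2.

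Of 5 decidual prolactin-family genes 4 fell mesometrially and 0 rose, including Prl8a2, decidual prolactin-related protein (3474 ± 5755 against 46300 ± 17910 CPM), Prl3c1 (63.0 ± 159.7 against 1029 ± 382 CPM) and the prolactin receptor gene Prlr (8.17 ± 3.25 against 14.3 ± 5.72 CPM; camera adjusted p = 0.0414). Without the library labelled control male mesometrial replicate 2 the mesometrial means of Prl8a2 and Prl3c1 were 1689 and 12.8 CPM. Of 20 ER stress and folding genes 15 fell and 2 rose, including the secretory regulator Xbp1 (308 ± 49.7 against 592 ± 126 CPM) and the chaperones Manf (195 ± 22.5 against 361 ± 63.5 CPM) and Pdia6 (679 ± 113 against 1220 ± 196 CPM; camera adjusted p = 4.59e-06). Decidualization regulators went both ways, 11 of 31 up and 15 down (camera adjusted p = 0.386). The transcription factor gene Hand2 (690.1 ± 248 against 1980 ± 488 CPM) and the small heat shock protein gene Cryab (328 ± 305 against 2248 ± 766 CPM) were lower mesometrially. Vascular endothelium genes also split, 14 of 20 up, including Eng (238 ± 42.9 against 131 ± 46.7 CPM) and Tek (62.7 ± 11.7 against 28.1 ± 13.9 CPM), and 4 down, including Plvap (86.0 ± 39.5 against 264 ± 77.0 CPM; camera adjusted p = 0.0671). Adjusted over the list alone, the counts were the same for each of these lists except ER folding, where 16 fell.

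**Figure D2:**
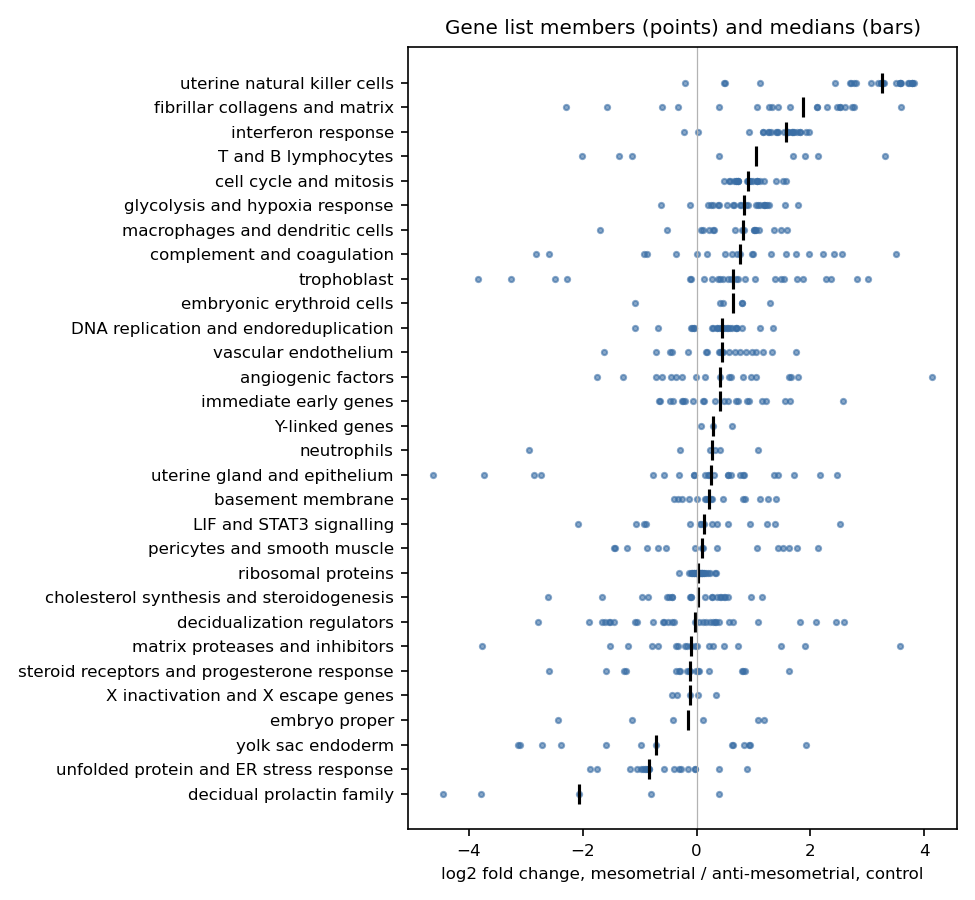
Log2 fold change of each tested member (points) of the gene lists between mesometrial and anti-mesometrial control decidua, with the median of each list as a black bar. Natural killer cell genes have a median of 3.27 and decidual prolactin-family genes a median of -2.07.

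A pair of libraries went against their compartment labels. On a scale built from 100 genes of each compartment, chosen without these 2 libraries, where 0 is the anti-mesometrial mean and 1 the mesometrial mean, the library labelled control male anti-mesometrial replicate 2 lay at 1.113, and the library labelled control male mesometrial replicate 2 at 0.565. The other mesometrial libraries ran from 0.893 to 1.156 and the other anti-mesometrial libraries from -0.103 to 0.225. Prl8a2 was 1015 CPM in the library labelled anti-mesometrial and 18470 CPM in the library labelled mesometrial. Both libraries were kept in the groups their titles give, and counts that changed by more than 1.5 times without them are given beside each comparison. Leaving out these libraries, or the cKO replicates numbered 4 and 5, was chosen after seeing the data.

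**Figure D3:**
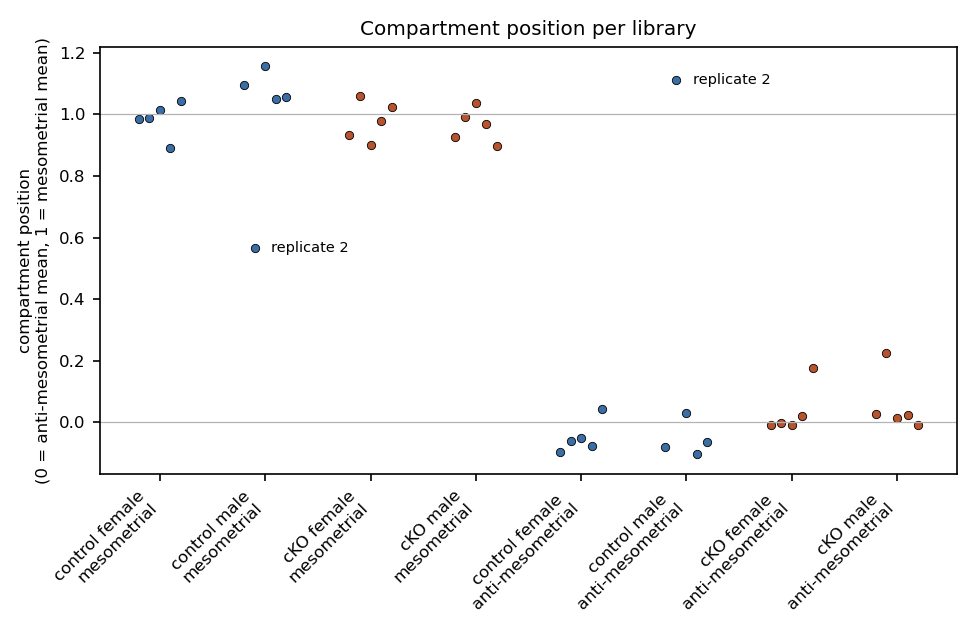
Position of each library on the scale from anti-mesometrial (0) to mesometrial (1), by labelled group (points are libraries, 5 per group, control in blue and cKO in red). The libraries labelled control male replicate 2 lie at 0.565 and 1.113.

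The comparison of cKO with control dams asks how the decidua responds to loss of uterine FOXA2, here with LIF given to cKO dams. In mesometrial decidua, Col6a5, Hapln1, Cdh10 and Prl8a9 rose in both sexes and Rpl29 fell. Col6a5, a collagen VI chain (chromosome 9, 105856078 to 105960643), stood 7.31-fold higher in cKO with female conceptuses (30.8 ± 2.82 against 4.202 ± 2.08 CPM, adjusted p = 3.67e-04) and 5.42-fold higher with male conceptuses (25.7 ± 5.14 against 4.70 ± 3.07 CPM, adjusted p = 0.00213; mean ± SD, cKO first, n = 5). Hapln1, which links hyaluronan to proteoglycans, rose 4.09-fold (44.5 ± 11.6 against 10.9 ± 1.87 CPM) and 2.90-fold (46.0 ± 14.2 against 15.8 ± 4.06 CPM). Prl8a9, a prolactin-family gene (chromosome 13, 27557995 to 27564606), rose 2.52-fold (25.7 ± 8.37 against 10.2 ± 2.08 CPM, adjusted p = 0.0137) and 2.91-fold (31.2 ± 6.74 against 10.7 ± 3.06 CPM, adjusted p = 0.00213). The cadherin gene Cdh10 rose 3.97-fold and 4.16-fold, and the ubiquitin ligase gene Hecw2 1.503-fold and 1.49-fold. Rpl29, a ribosomal protein gene (chromosome 9, 106429454 to 106431568), fell in both, by 1.87-fold with female (358 ± 42.3 against 670.0 ± 156 CPM) and 1.62-fold with male conceptuses (373 ± 20.2 against 607 ± 45.3 CPM). Igsf9, an immunoglobulin-superfamily adhesion gene, fell by 1.54-fold and 1.89-fold.

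With female conceptuses the receptor gene Gpr37 (3.09 ± 0.963 against 0.921 ± 0.470 CPM), the neural adhesion gene Chl1 (63.5 ± 10.1 against 31.6 ± 5.15 CPM) and Gpr155 (12.6 ± 1.88 against 7.22 ± 1.05 CPM) were also among the largest mesometrial rises. With male conceptuses the actin-associated adaptor gene Eps8l1 (8.12 ± 3.10 against 2.43 ± 0.583 CPM), the growth-associated gene Gap43 (15.1 ± 6.97 against 6.07 ± 1.39 CPM), Pcsk1n, which encodes an inhibitor of prohormone convertase (5.26 ± 1.71 against 2.70 ± 0.547 CPM), and the protease inhibitor gene Serpinb1a (22.6 ± 2.89 against 11.9 ± 4.63 CPM) rose. Falls with male conceptuses included Cyp1a1, the aryl hydrocarbon receptor-induced cytochrome P450 (1.65 ± 0.535 against 4.53 ± 1.18 CPM), the signalling ligand gene Wnt10b (1.39 ± 0.380 against 3.46 ± 1.28 CPM), the collagen VI gene Col6a3 (90.1 ± 27.4 against 221 ± 32.8 CPM), and the endocytic receptor gene Lrp2 (8.28 ± 2.93 against 19.02 ± 3.18 CPM). Others were Pla1a (13.3 ± 5.06 against 29.4 ± 9.87 CPM), Prrt1 (3.47 ± 1.06 against 7.51 ± 2.43 CPM) and Fndc1 (9.25 ± 1.75 against 19.5 ± 3.62 CPM; mean ± SD, n = 5). Of 16804 genes, 14 rose and 3 fell with female conceptuses and 44 rose and 87 fell with male conceptuses (edgeR quasi-likelihood test, adjusted p under 0.05). Of these, 9 rises were called in both sexes, where independent lists would share 0.0367, and 2 falls, where they would share 0.0155. These values leave out that same-numbered female and male cKO libraries deviated together (correlations of 0.462 to 0.864). Leaving out single libraries gave with female conceptuses 9, 26 and 30 genes without control 3, 4 and 5, and 10 without cKO 4 or 5. With male conceptuses it gave 56 without control 4, and 28 (19 up), 20 (11 up), 59 and 43 without cKO 1, 2, 3 and 5. Without both control male replicate 2 libraries the female count was 41, and without cKO replicates 4 and 5 the male count was 77, with 5 of the 17 female and 35 of the 131 male calls kept. Lost then were the female calls of Prl8a9, Cdh10, Hecw2, Igsf9, Gpr37, Chl1 and Gpr155 (adjusted p from 0.0576 to 0.174) and the male calls of Rpl29, Eps8l1, Serpinb1a, Wnt10b, Pla1a and Prrt1 (0.0576 to 0.134). With each library left out in turn, calls were kept for Col6a5, Hapln1, Prl8a9, Rpl29 and Gpr155 with female conceptuses. With male conceptuses they were kept for Col6a5, Hapln1, Prl8a9, Cdh10, Igsf9, Eps8l1 and Fndc1. The other genes named here lost a call without at least 1 library (adjusted p up to 0.183 with female and 0.121 with male conceptuses). Gap43 and Pcsk1n lost theirs without both control male replicate 2 libraries.

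In anti-mesometrial decidua, Prl8a9, Pyy, Tmem45a, Klk8 and Klk9 rose with either sex of conceptus, and Slc7a8, Slc3a2 and Prss29 fell. Prl8a9 rose 8.49-fold with female (71.8 ± 29.2 against 8.43 ± 5.37 CPM, adjusted p = 0.00197) and 11.5-fold with male conceptuses (92.7 ± 33.1 against 8.02 ± 3.56 CPM, adjusted p = 3.48e-04; mean ± SD, cKO first, n = 5). Pyy, which encodes peptide YY, stood at 5.68 ± 3.16 against 0.230 ± 0.338 CPM and 7.63 ± 6.70 against 0.303 ± 0.280 CPM. Tmem45a rose 5.43-fold (56.5 ± 35.4 against 10.4 ± 1.59 CPM) and 6.27-fold (64.8 ± 48.5 against 10.3 ± 2.02 CPM). The neighbouring kallikrein protease genes Klk8 (20.1 ± 6.72 against 6.63 ± 2.14 CPM and 20.3 ± 6.41 against 6.73 ± 1.45 CPM) and Klk9 (24.6 ± 6.05 against 8.31 ± 1.13 CPM and 26.8 ± 8.28 against 8.41 ± 3.57 CPM) rose in both. Eps8l1 rose 2.97-fold and 4.85-fold, Shisa2 3.73-fold and 4.44-fold, and Gad1, which encodes a GABA-synthesising enzyme, 2.28-fold and 2.07-fold. The low-level genes Tpsg1, a mast cell tryptase, and Ear6, an eosinophil-associated ribonuclease, averaged 1.003 and 0.0220 CPM and 1.18 and 0.0117 CPM in female cKO and control decidua.

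Slc7a8 and Slc3a2, the light and heavy chains of an amino acid transporter, fell in both sexes. Slc7a8 stood at 102 ± 6.83 against 192 ± 55.1 CPM with female and 89.1 ± 8.96 against 243 ± 65.0 CPM with male conceptuses, and Slc3a2 at 143 ± 19.7 against 215 ± 28.1 CPM and 136 ± 13.8 against 224 ± 18.1 CPM. Pfkfb3, a regulator of glycolysis (8.77 ± 1.94 against 15.1 ± 1.97 CPM and 8.84 ± 0.740 against 14.0 ± 1.75 CPM), the ectonucleotidase gene Entpd3 (2.59 ± 0.417 against 6.88 ± 2.31 CPM and 2.72 ± 0.441 against 7.40 ± 2.21 CPM) and Rpl29 (234 ± 19.9 against 427 ± 16.1 CPM and 255 ± 13.7 against 447 ± 46.0 CPM) also fell in both. The gland protease gene Prss29 averaged 0.0223 ± 0.0499 against 3.07 ± 1.79 CPM with female (adjusted p = 0.0138) and 0.00947 ± 0.0212 against 1.56 ± 1.37 CPM with male conceptuses (adjusted p = 0.0122). With female conceptuses Wfdc5, a whey acidic protein-domain gene, also rose (8.67 ± 3.22 against 2.15 ± 0.851 CPM). With male conceptuses the tryptase gene Tpsb2 (27.2 ± 18.0 against 1.69 ± 1.43 CPM), the syntenin gene Sdcbp2 (6.72 ± 1.59 against 1.76 ± 0.753 CPM) and Rasgef1b (9.18 ± 4.97 against 2.85 ± 0.463 CPM) rose. Mamdc2 (7.45 ± 1.65 against 19.5 ± 10.2 CPM), the collagen receptor gene Mrc2 (15.6 ± 1.94 against 33.4 ± 7.08 CPM) and Ltbp3, a binding protein of latent TGF-beta (106 ± 19.5 against 215 ± 51.3 CPM), fell. Of 15705 genes, 22 rose and 8 fell with female and 42 rose and 34 fell with male conceptuses (edgeR, adjusted p under 0.05). Called in both sexes were 16 rises and 6 falls, where independent lists would share 0.0588 and 0.0173. Here too same-numbered cKO libraries of both sexes deviated together (correlations of 0.403 to 0.796). With female conceptuses the count was 6, 5, 5 and 8 without control 1, 2, 3 and 4, and 18, 10, 14 and 12 without cKO 1, 3, 4 and 5. With male conceptuses it was 39, 368 and 47 without control 1, 2 and 3, and 41, 39 and 44 without cKO 1, 4 and 5. Without both control male replicate 2 libraries the counts were 185 and 368, and without cKO replicates 4 and 5 the male count was 148, with 14 of the 30 female and 40 of the 76 male calls kept. Lost then were the female calls of Klk9, Eps8l1, Shisa2, Gad1, Slc7a8, Slc3a2, Pfkfb3, Entpd3 and Prss29 (adjusted p from 0.0535 to 0.173) and the male calls of Klk9, Gad1, Prss29, Ear6, Rasgef1b, Mamdc2 and Ltbp3 (0.0513 to 0.081). With each library left out in turn, calls were kept for Prl8a9, Rpl29 and Prss29 with female conceptuses. With male conceptuses they were kept for Prl8a9, Pyy, Tmem45a, Klk8, Klk9, Eps8l1, Shisa2, Tpsg1, Slc7a8, Slc3a2, Entpd3, Rpl29, Tpsb2, Sdcbp2 and Mrc2. The other genes named for this part lost a call without at least 1 library (adjusted p up to 0.197 with female and 0.129 with male conceptuses).

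Atp2c1, a Golgi calcium and manganese pump gene (chromosome 9, 105403539 to 105527319), was higher in cKO in all 4 strata, from 1.26-fold in male mesometrial to 1.38-fold in male anti-mesometrial decidua. With Prl8a9 and the falling Rpl29, it was called in every stratum. Without cKO replicates 4 and 5 the calls of Atp2c1 were lost in both mesometrial strata (adjusted p = 0.114 and 0.112), that of Prl8a9 in the female (0.0716) and that of Rpl29 in the male one (0.0576). Leaving out 1 library ended the calls of Atp2c1 in male mesometrial and female anti-mesometrial decidua in 6 and 4 of 10 cases. The processed pseudogenes Tma7-ps and Gm8210, chosen after their values were seen, were called in every stratum too, with log2 fold changes from 2.71 to 3.89 and from 3.15 to 5.54. Genes of near-identical copies, such as Rpl29, these pseudogenes, the Klk, Tps, Prss, Ear and Prl families and granzymes, are uncertain, because the handling of multiply mapped reads is not given in the sources used here. The strand setting is not given either, so overlapping and antisense genes could not be separated.

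Cell cycle genes lay higher in cKO with female conceptuses in both compartments. All 24 had positive values, with medians of 0.32 mesometrially (camera adjusted p = 4.32e-11) and 0.36 anti-mesometrially (camera adjusted p = 2.22e-09; adjusted p = 0.895 and 0.558 with an estimated correlation). No member passed over all genes, and 9 and 4 did adjusted over the list alone, among them Kif20a (35.6 ± 5.72 against 25.2 ± 3.48 CPM) and Ttk (15.8 ± 3.51 against 11.5 ± 0.680 CPM) mesometrially and Nusap1 (21.1 ± 2.05 against 13.7 ± 1.20 CPM) anti-mesometrially. With male conceptuses the list passed mesometrially (median 0.21, camera adjusted p = 5.45e-04; adjusted p = 0.844 with an estimated correlation), not anti-mesometrially (0.259). In the fit without both control male replicate 2 libraries it passed anti-mesometrially (5.71e-05) and not mesometrially (0.191), and leaving out the mesometrial one alone ended that call too. Cholesterol synthesis genes lay lower in all 4 strata, with medians of -0.15, -0.32, -0.39 and -0.42 in female mesometrial, male mesometrial, female anti-mesometrial and male anti-mesometrial decidua (camera adjusted p = 0.0123, 4.26e-05, 1.09e-04 and 1.79e-05). With an estimated correlation the adjusted p was 0.895, 0.844, 0.558 and 0.721. Adjusted over the list alone, 9 of 22 members fell in male mesometrial decidua, with Hmgcs1 at 122 ± 22.7 against 163 ± 8.11 CPM and Sqle at 70.7 ± 8.10 against 91.1 ± 9.63 CPM, and 2 in male anti-mesometrial decidua, with the regulator Srebf2 at 129.8 ± 19.97 against 193 ± 19.7 CPM. Without cKO replicates 4 and 5 the cholesterol list passed in no stratum (camera adjusted p from 0.213 to 0.870) and pointed up in female anti-mesometrial decidua. Its female mesometrial call was also lost without control 2 or 3 or cKO 4 or 5 alone (0.0851 to 0.242), and its female anti-mesometrial median was -0.24 without cKO 4 and -0.21 without cKO 5. Vascular endothelium genes lay higher with female conceptuses (medians 0.21 and 0.35, camera adjusted p = 0.00348 and 1.19e-04; adjusted p = 0.895 and 0.558 with an estimated correlation), with Emcn at 125 ± 13.7 against 98.0 ± 8.10 CPM mesometrially and Ets1 at 55.1 ± 3.87 against 37.2 ± 4.96 CPM anti-mesometrially. Adjusted over the list alone, 3 of them rose and 1 fell mesometrially and 1 rose anti-mesometrially. The mesometrial call was lost without control 5 (0.0577) or cKO 3 (0.0698). Interferon-response genes did likewise, with 0 members past either threshold (medians 0.13 and 0.49, camera adjusted p = 0.0123 and 8.35e-05; adjusted p = 0.895 and 0.558 with an estimated correlation). Their mesometrial call was lost without control 1 or 3 or cKO 2 or 3 (0.0527 to 0.239), with a median of 0.21 without control 5. Ribosomal protein genes lay lower in all strata but male mesometrial, with medians of -0.36, -0.21 and -0.13 (camera adjusted p = 6.53e-11, 7.25e-12 and 4.49e-05; adjusted p = 0.895, 0.558 and 0.721 with an estimated correlation). In female mesometrial decidua control replicate 5 had 55070 CPM of these genes, against 25680 to 26920 CPM in the other 4 controls. Without it the median was -0.09 (camera adjusted p = 0.00904). The male anti-mesometrial ribosomal call was lost without cKO replicates 4 and 5 (camera adjusted p = 0.257), and its median was -0.08 without cKO 4.

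Collagen and matrix genes lay lower with male conceptuses, with medians of -0.42 mesometrially (19 of 20 negative, camera adjusted p = 4.26e-05) and -0.71 anti-mesometrially (16 of 19 negative, 0.00730), and adjusted p = 0.844 and 0.721 with an estimated correlation. In male mesometrial decidua Col6a3 fell over all genes and 3 members fell adjusted over the list alone, where Fn1, fibronectin, stood at 707 ± 202 against 1665 ± 240.0 CPM. The anti-mesometrial call was lost without control male anti-mesometrial replicate 2 alone, as without both libraries of that number (camera adjusted p = 0.534). Uterine natural killer cell genes lay lower mesometrially in both sexes (medians -0.24 and -0.26, camera adjusted p = 0.0123 and 0.0489; adjusted p = 0.895 and 0.844 with an estimated correlation). Their granzyme gene Gzma stood at 210.0 ± 42.6 against 380.4 ± 284 CPM and 203 ± 54.8 against 290.2 ± 86.5 CPM, and without cKO replicates 4 and 5 the list's direction turned (camera adjusted p = 0.88 and 0.648). Those 4 mesometrial libraries had summed killer cell gene levels of 3005 and 3512 CPM in female and 3400 and 2513 CPM in male decidua, against 6259 to 8725 CPM in the other cKO mesometrial libraries. With single libraries left out the female call was lost without control 5 (0.48) or cKO 4 (0.217) or 5 (0.242), and the male call without control 1, 3 or 5 or cKO 4 or 5 (0.0712 to 0.363). The female median was -0.38 and -0.37 without cKO 2 and 3, and the male median -0.41 without control 2. Trophoblast genes lay lower in female mesometrial (median -0.62, camera adjusted p = 0.0123; adjusted p = 0.895 with an estimated correlation) and higher in male anti-mesometrial decidua (median 1.25, camera adjusted p = 1.79e-05; adjusted p = 0.721 with an estimated correlation). Without cKO replicates 4 and 5 the female mesometrial call was lost (camera adjusted p = 0.870), as it was without control 3 (0.197), cKO 4 (0.217) or cKO 5 (0.181), with medians of -0.94 without control 5 and -0.96 without cKO 1. Summed trophoblast genes were 3362 and 2888 CPM in cKO male anti-mesometrial replicates 1 and 2 (others 584 to 1025), where Y-linked genes of the conceptus were 15.5 and 12.9 CPM (others 0.709 to 3.73). The group means of Y-linked genes were 6.81 CPM in cKO and 2.38 CPM in control. Adjusted over the list alone, 6 of 21 trophoblast genes rose and 1 fell in male anti-mesometrial decidua. Prl8a9, also a member of that list, rose in both. The placental proteases Mmp9 stood at 61.9 ± 21.2 against 21.2 ± 15.3 CPM in male anti-mesometrial decidua and Cts7 at 62.8 ± 17.8 against 20.1 ± 9.83 CPM in female anti-mesometrial decidua, neither past the threshold over all genes. Among gland and epithelium genes 1 of 21 fell in male mesometrial decidua, the antimicrobial lipocalin gene Lcn2 (16.8 ± 2.54 against 30.2 ± 9.22 CPM). In female anti-mesometrial decidua Prss29 and Spink1 fell, 2 of 22, the latter with 0 CPM in each of the 5 cKO libraries and 1.54 ± 0.865 CPM in control (camera adjusted p = 0.462 and 0.121). Without cKO replicates 4 and 5 the calls of Lcn2 and Spink1 were lost (adjusted p = 0.128 and 0.140), as they were without 7 and 9 of 10 single libraries. No decidual prolactin-family gene passed in any stratum (camera adjusted p from 0.151 to 0.965), and Prl8a2 averaged 31370 ± 10060 against 48440 ± 6457 CPM with female and 35600 ± 8382 against 31300 ± 17100 CPM with male conceptuses anti-mesometrially. Without control male anti-mesometrial replicate 2 that control mean was 38920 CPM, above cKO.

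The series asks whether these effects depend on the sex of the conceptus. The male minus female difference of the cKO effect passed for 0 of 16804 genes in mesometrial and 0 of 15705 genes in anti-mesometrial decidua (edgeR, adjusted p under 0.05), with 798 and 397 genes at an unadjusted p under 0.05. DESeq2 called 1 gene in each, the pseudogene Gm8210 mesometrially and the embryonic globin gene Hba-x anti-mesometrially, both chosen after their values were seen. Of the 137 genes called in either sex mesometrially 129 had the same sign in both, and all 84 anti-mesometrially did. Among the genes not called 62.2% and 64.8% had the same sign, and over all genes the log2 fold changes of the 2 sexes correlated at 0.307 and 0.470 (Pearson). Same-numbered cKO libraries deviated together, so the sexes are not independent. Among lists, trophoblast genes stood relatively higher in the male effect in both compartments, with median differences of 0.95 and 0.91 (camera adjusted p = 0.00476 and 0.00351; adjusted p = 0.888 and 0.661 with an estimated correlation), with no member past either threshold. The mesometrial call was lost without control female 3 (0.0567), cKO female 4 (0.0758) or 5 (0.0624) or cKO male 1 (0.0897), and the anti-mesometrial call without cKO male 1 (0.190). The trophoblast genes Psg19 and Rhox9 differed by 1.20 (SE 0.68) and 2.95 (SE 1.49) mesometrially on the log2 scale. Collagen genes stood relatively lower, with median differences of -0.26 and -1.10 (camera adjusted p = 0.00476 and 0.00150; adjusted p = 0.888 and 0.636 with an estimated correlation), and the anti-mesometrial call was lost without control male anti-mesometrial replicate 2 (0.528). The mesometrial call was lost without control female replicate 5 (median -0.08, camera adjusted p = 0.423), and its median was -0.40 without cKO male replicate 4. Simulated log2 differences of 1 were recovered for 69% and 46% of genes (mesometrial first), of 2 for 95% and 89%. Real shares may be lower where genes vary together or counts are low (edgeR did not call Y-linked Eif2s3y).

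**Figure D4:**
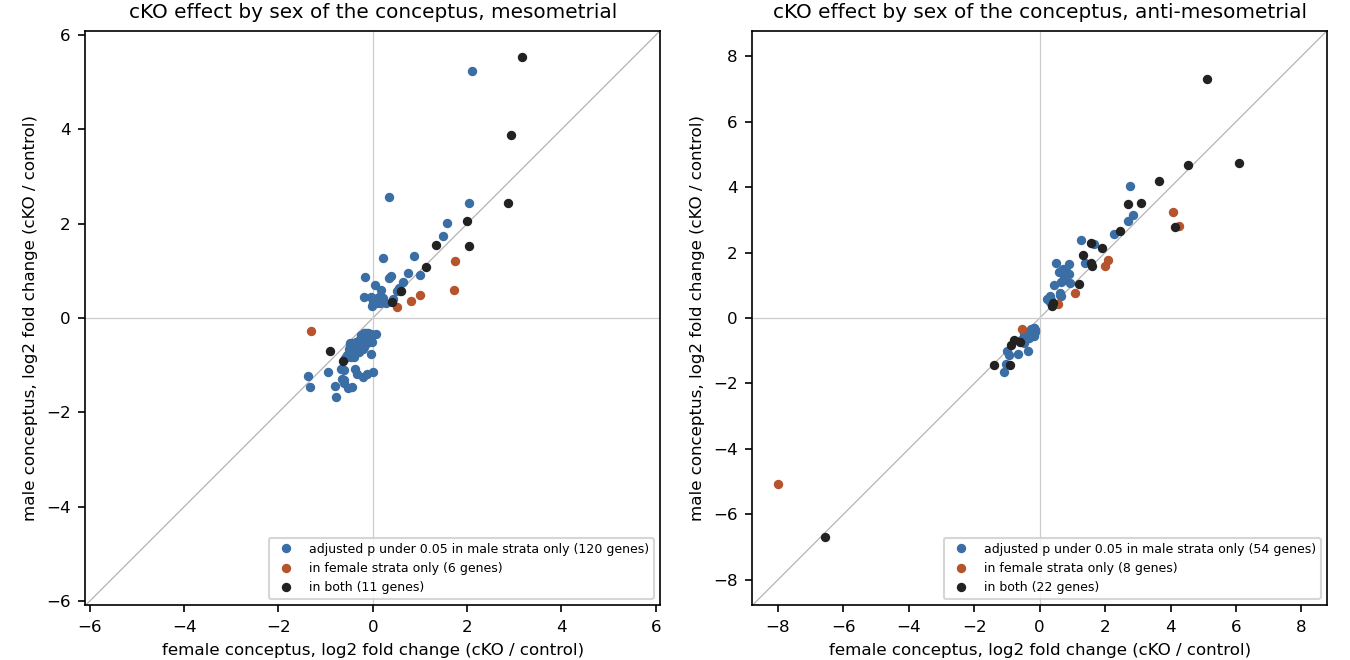
Log2 fold change of cKO against control with female (x axis) and male (y axis) conceptuses, for genes past adjusted p 0.05 in at least 1 sex, mesometrial left and anti-mesometrial right. Points are genes, in blue when called with male conceptuses only, in red with female only and in black with both, and the diagonal marks equal values. Fold changes of genes with a group at or near 0 counts depend on the prior count.

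Male and female conceptuses were also compared within each genotype. The Y-linked genes Eif2s3y (chromosome Y, 1010543 to 1028847) and Ddx3y were detected with male conceptuses, at 1.33 ± 0.563 against 0.0115 ± 0.0257 CPM and 1.56 ± 0.722 against 0 ± 0 CPM in control mesometrial decidua (male first, mean ± SD, n = 5), and neither passed over all genes (adjusted p = 0.412 and 0.476, edgeR). Xist, the RNA of the inactive X chromosome, which the dam's own tissue also carries, stood at 1163 ± 285 against 1699 ± 1171 CPM in control and 901 ± 40.9 against 1142 ± 249.9 CPM in cKO mesometrial decidua. Xist in control female mesometrial replicate 5 was 3825 CPM against 967 to 1551 CPM in the other 4 libraries of that group. The trophoblast genes Rhox9 (7.08 ± 2.84 against 36.1 ± 27.7 CPM) and Plac1 (15.6 ± 5.05 against 45.4 ± 30.9 CPM) had lower values with male conceptuses in control mesometrial decidua, neither past the threshold. Among lists, ribosomal protein genes lay lower with male conceptuses in control mesometrial decidua (median -0.41, 0 of 30 positive, 15 lower adjusted over the list alone, camera adjusted p = 1.03e-15; adjusted p = 0.701 with an estimated correlation). Without control female replicate 5 (55070 CPM of these genes, other 4 25680 to 26920) the median was -0.15, with 3 of 30 positive and 0 lower adjusted over the list alone (camera adjusted p = 3.41e-06). No gene was called in control mesometrial, cKO mesometrial, control anti-mesometrial or cKO anti-mesometrial decidua (edgeR), with 1638, 185, 1097 and 95 genes at an unadjusted p under 0.05. DESeq2 called 5, 2, 2 and 4 genes, with Eif2s3y among each of them.

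The difference of the cKO effect between compartments passed for 1 of 17495 genes, Prl8a9, whose rise was smaller mesometrially (log2 difference -1.87 (SE 0.33), adjusted p = 0.0428, edgeR), with 1400 genes at an unadjusted p under 0.05 and 48 called by DESeq2. Other trophoblast genes pointed the same way without passing over all genes, with Mmp9 at -1.56 (SE 0.47), Psg19 at -1.42 (SE 0.49) and Cts8 at -1.73 (SE 0.60). The trophoblast list had a median difference of -1.16 (23 of 26 negative, camera adjusted p = 3.04e-06; adjusted p = 0.85 with an estimated correlation), with 5 members lower adjusted over the list alone, and a median of -0.62 with 2 such members without cKO male anti-mesometrial replicate 1. Pericyte and smooth muscle genes had a median difference of -0.37 (14 of 16 negative, camera adjusted p = 0.00279; adjusted p = 0.85 with an estimated correlation), with Notch3 at -0.48 (SE 0.22) and Lmod1 at -1.75 (SE 0.51) and 1 member lower adjusted over the list alone, and a median of -0.23 without cKO male anti-mesometrial replicate 5 or control male mesometrial replicate 2. Without both control male replicate 2 libraries 587 genes were called, 319 with a higher and 268 with a lower effect mesometrially, Mmp9 and Lmod1 among them, and without cKO replicates 4 and 5 the count was 0. With same-numbered mesometrial and anti-mesometrial libraries as a block 4 genes were called, Prl8a9 among them, and leaving out 1 library at a time gave from 0 to 131.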

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

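In this part the tests of exchanged labels, mixed tissue, library size, a shared dam or day and strain DNA, that of genes alike in both compartments, the levels set beside the pseudogenes, the lists without single libraries and the splits that keep same-numbered libraries together were chosen after the results were seen. The tests of compartment position in cKO replicates 4 and 5, of the closest match of the pseudogenes and of the other splits were set before their results were known.

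The libraries labelled control male replicate 2 stood apart from their groups in compartment position, at 0.565 for the one labelled mesometrial (others 1.05 to 1.16) and 1.11 for the one labelled anti-mesometrial (others -0.103 to 0.0311). An exchange of the 2 labels alone is argued against, because the library labelled mesometrial, at 0.565, lay above the highest other anti-mesometrial library at 0.225, and library size is argued against by 0 of 2 totals outside the range of the others. Mixed tissue in the library labelled mesometrial may account for its place, as its median mesometrial share was 0.647 over 100 mesometrial genes (quartiles 0.567 to 0.758) and 0.513 over 100 anti-mesometrial genes (0.432 to 0.601), a difference of 0.134 with overlapping quartiles. These shares are on the CPM scale, on which mixing adds up, and replaced log-scale positions of 0.841 and 0.288 after those had been seen, so the choice of scale matters to this reading. Whether mixing came together with an exchange stays open, and no biological explanation was tested, because the design sets no group apart here.

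The cKO replicates 4 and 5 stood apart from 1 to 3 in both sexes. Mesometrially, summed trophoblast genes were 344 to 421 against 1289 to 3225, and Y-linked genes in male libraries 0.224 and 0.375 against 5.23 to 16.95 CPM. Bmp2 was 962 to 1072 against 553 to 661 CPM (controls 636 to 924). Anti-mesometrially it was 1344 to 1421 against 401 to 602 CPM (controls 642 to 862). The cKO means average both sets. Library size is argued against, with 0 of 8 totals outside the range of the other 12 cKO libraries. Compartment position cannot decide on a different division, as 1 of 8 libraries, cKO male mesometrial replicate 5, lay beyond the others (0.897 against 0.8995). Over 2824 genes alike in both compartments of controls (absolute log2 fold change under 0.2), which another division would move little, replicates 4 and 5 of different cKO groups still correlated at 0.383 to 0.769, against -0.724 to -0.0610 with replicates 1 to 3. A shared dam or dissection day may underlie the likeness, since same-numbered cKO libraries correlated at 0.211 or more, but differently numbered ones reached 0.650 to 0.869 between cKO groups, no label gives a dam or day, and the values leave this open. No biological explanation was tested, because no group of the design parts these replicates.

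Of 28 genes called in both sexes in at least 1 compartment, Atp2c1, Col6a5, Rpl29 and Entpd3 lay within 20 Mb of Ltf on chromosome 9, that is 4 where 0.532 were expected among 17160 genes (Fisher's exact p = 0.00183), and 0 of 41 other windows of equal gene number held as many (highest 3). Strain DNA carried along with the iCre insertion is a candidate explanation, as a hypothesis, and an effect of Foxa2 loss on these genes stays open and untested, whereas library size is argued against by a smallest exact permutation p of 0.127 over the 4 strata (cKO against control totals, n = 5). Reads of a chromosome 9 gene counted for a similar pseudogene cannot be told apart, as the closest match lay in the window for 1 of 2 pseudogenes chosen after their values were seen, Tma7 for Tma7-ps (98.97% identical). A closest match elsewhere had been set as evidence against, wrongly, because Gm13841 on chromosome 5, the closest to Gm8210 (100%, Rpl29 99.38%), had 4808 counts over all libraries and Rpl29 322503. Tma7 and Rpl29 stood at 91.5 CPM or more in cKO, above the rises of 6.31 to 10.8 CPM of the pseudogenes, but Rpl29 fell by 191 to 261 CPM, and Gm8210 rose by at most 7.73 CPM.

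Single libraries far from the other 4 of their group were found in 20 of 120 sets of library values, where chance gives about 1 in 20. In control female mesometrial decidua these were replicate 5 for Xist (3825 CPM, others 967 to 1551), natural killer cell genes (12910 CPM, others 6057 to 7296) and ribosomal protein genes (55070 CPM, others 25680 to 26920), and replicate 4 for the prolactin family (5324 CPM, others 1553 to 2315). The library labelled control male mesometrial replicate 2 had 1.80 CPM of Foxa2 (others at most 0.150) and 18980 CPM of prolactin-family genes (others 586 to 1386). The library labelled control male anti-mesometrial replicate 2 had 0.0945 CPM of Foxa2 (others 1.33 to 1.45), 3.31 CPM of Lif (others 0.154 to 0.897), 11430 CPM of natural killer cell genes (others 64.1 to 82.7), 1032 CPM of prolactin-family genes (others 34570 to 39000) and 27020 CPM of ribosomal protein genes (others 18120 to 19620). Ltf was 11.1 CPM in control male anti-mesometrial replicate 3 (others 0.897 to 1.98) and Foxa2 0.489 CPM in cKO female mesometrial replicate 3 (others 0.0491 to 0.166). Control female anti-mesometrial replicate 2 had 352 CPM of yolk sac genes (others 128 to 149) and 233 CPM of embryonic erythroid genes (others 48.6 to 78.9), and replicate 5 had 497.5 CPM of natural killer cell genes (others 74.2 to 106). Compartment positions of 0.176 in cKO female anti-mesometrial replicate 5 (others -0.00899 to 0.0204) and 0.225 in cKO male anti-mesometrial replicate 2 (others -0.00700 to 0.0262) also stood apart.

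Over the named genes, 265 of 1898 sets of group values (13.96%, against 5% by chance) had 1 library far from the rest. The library labelled control male anti-mesometrial replicate 2 accounted for 99 of them, control female mesometrial replicate 5 for 41, the library labelled control male mesometrial replicate 2 for 35, control female anti-mesometrial replicate 5 for 19, cKO male anti-mesometrial replicate 2 for 15 and control female mesometrial replicate 4 for 7. Of the 27 libraries with any, the others had 1 to 5 each.

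Differences between groups in the cKO effect passed camera for lists, and for Prl8a9 by edgeR (log2 difference -1.87 between compartments). For the male minus female difference the median log2 differences were 0.95 for trophoblast, 0.47 for ribosomal protein, -0.26 for collagen and -0.23 for basement membrane genes in mesometrial decidua (camera adjusted p from 3.24e-15 to 0.00702; adjusted p = 0.888 with an estimated correlation). Without control female mesometrial replicate 5 the ribosomal median was 0.21 (camera adjusted p = 6.94e-08), and the collagen and basement membrane calls were lost (medians -0.08 and -0.03, camera adjusted p = 0.423 and 0.597). The trophoblast call was lost without control female 3, cKO female 4 or 5 or cKO male 1 (0.0567 to 0.0897). In anti-mesometrial decidua they were 0.91 for trophoblast, 0.86 for prolactin-family, 0.57 for gland, 0.56 for yolk sac, 0.48 for neutrophil and 0.0603 for ribosomal protein genes, and -1.10 for collagen, -0.61 for interferon-response, -0.51 for glycolysis and -0.34 for cell cycle genes (camera adjusted p from 2.06e-08 to 0.0489; adjusted p from 0.567 to 0.696 with an estimated correlation). Without control male anti-mesometrial replicate 2 the collagen and cell cycle calls were lost and the interferon list pointed up (camera adjusted p = 0.528, 0.148 and 0.784), and the prolactin-family and glycolysis medians were 0.55 and -0.17. The interferon call was lost without cKO male 5 (0.0557), trophoblast without cKO male 1 (0.190), yolk sac without control female 2 (0.1001), gland without control male 4 (0.0951) or cKO female 4 (0.0675), and neutrophils without control female 5 (0.0606), cKO female 4 (0.0675) or cKO male 3 (0.101). The gland median was 0.375 and 0.341 without control female 1 and 2, and the cell cycle median -0.22 without cKO male 1. The neutrophil median was 0.295 without control female 2 and 0.768 to 0.829 without control male 3, cKO female 2 or 3 or cKO male 4 or 5. The ribosomal call was lost without any 1 of control female 3 or 5, control male 4 or 5, cKO female 1 or 2 or cKO male 1, 2 or 3 (0.0569 to 0.321), and its median was 0.104 to 0.127 without cKO female 4 or 5 or cKO male 4 or 5. Between compartments they were -1.16 for trophoblast, -0.37 for pericyte, 0.14 for cholesterol synthesis and -0.14 for immediate early genes (camera adjusted p from 3.04e-06 to 0.047; adjusted p = 0.85 with an estimated correlation). With 1 of the 40 libraries left out at a time, the cholesterol call was lost in 16 cases (0.0502 to 0.262) and the immediate early call in 22 (0.0503 to 0.112), and the other 2 were not lost. The cholesterol median was 0.208 to 0.233 without control male mesometrial 2 or 1 of anti-mesometrial cKO 1, 2 or 3 of either sex, and the immediate early median -0.244 without control male anti-mesometrial 2.

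Other splits of the same libraries into groups of equal sizes were counted, 100 for fits within a compartment and 60 for fits of all libraries, the labelled split included. For cKO against control, 2, 1, 1 and 2 of 100 splits gave as many genes as the labelled 17, 131, 30 and 76. The highest of the others were 304, 43, 0 and 1521 (female and male mesometrial, female and male anti-mesometrial decidua). The splits with 304 and 1521 genes point to a structure of the samples other than genotype. Splits treat libraries as independent, which no label shows, so chance is not excluded. For the compartment comparison only the labelled split gave as many (1 of 60, 11201 against 7289). For the difference between compartments 2 of 60 splits gave as many genes (1 against 3), but 5 of 60 did when same-numbered libraries of both compartments were kept together (1 against 4), and the count was 0 without cKO replicates 4 and 5, so chance cannot be excluded. For the 0 genes of the male minus female difference and of male against female the splits test nothing, because each of 100 splits gives at least 0. Their highest counts, 529 and 667 for the difference and 1351, 1312, 48 and 1493 for male against female (control mesometrial, cKO mesometrial, control anti-mesometrial and cKO anti-mesometrial decidua), point to a structure of the samples. Among the 16 splits that part every numbered pair, the highest other counts in the cKO male against female comparisons, where the numbers pair the libraries, were 0 in both compartments.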

How the results depend on the processing

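Leaving out both control male replicate 2 libraries or cKO replicates 4 and 5, the block in the fit of 2 groups, the block for lists and single libraries left out for Y-linked counts and lists were chosen after the data were seen, and all other settings were planned. Genes listed here because a count was small were chosen after their values were seen. Counts of called genes are given for cKO against control in female mesometrial, male mesometrial, female anti-mesometrial and male anti-mesometrial decidua in that order, with 17, 131, 30 and 76 in the edgeR fit described. DESeq2 called 121, 581, 163 and 323 genes, which included all of the edgeR calls. RLE factors gave 17, 136, 33 and 76. Without a low-count filter, which roughly doubled the genes adjusted for, the counts were 18, 33, 17 and 49. With only the 2 groups compared they were 9, 38, 65 and 22. Without both control male replicate 2 libraries they were 41, 182, 185 and 368, and 17, 108, 30 and 76 of the calls above were kept. Without cKO replicates 4 and 5 they were 12, 77, 37 and 148, with 5, 35, 14 and 40 kept. The causes were not tested, apart from the number of libraries and genes each setting leaves.

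The replicate numbers did not pair cKO with control libraries, and a block of numbers gave 46, 225, 59 and 193 genes, with 16, 126, 26 and 75 shared with the fit without it. Together with only the 2 groups it gave 5, 11, 87 and 6. The 5 female mesometrial genes were Gm8210, Tma7-ps, Col6a5, Serpinb1a and Hapln1. In the male against female comparisons in cKO, where every same-numbered pair correlated above 0.1, the block changed no count (0 each). In the compartment comparison, where same-numbered female and not male controls correlated above 0.1, it gave 11731 against 11201. The block ended the calls of Gpr37, Gap43, Pcsk1n, Shisa2, BC037034 and Spink1 in 1 comparison each.

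The difference of the cKO effect between compartments gave 1 gene in the edgeR fit and without a filter, 6 with RLE factors (Mreg, Bicc1, Prl8a9, Nim1k, Lifr and Eif2b5), 4 with the block (Il1r2, Bco1, Prl8a9 and Slc7a8), 48 with DESeq2, 587 without both control male replicate 2 libraries and 0 without cKO replicates 4 and 5. The male minus female difference of the cKO effect stayed at 0 genes in every setting except DESeq2, with 1 in each compartment. Apart from single libraries left out, male against female gave 0 genes in each edgeR setting except control mesometrial without cKO replicates 4 and 5 (1, Eif2s3y) or with only the 2 groups (1, Eif2s3y), and cKO mesometrial without cKO replicates 4 and 5 (2, Eif2s3y and Ddx3y). DESeq2 gave 5, 2, 2 and 4 in control mesometrial, cKO mesometrial, control anti-mesometrial and cKO anti-mesometrial decidua. The compartment comparison stayed between 10851 and 11923 genes in all settings, single libraries left out included. The 78 list calls over all comparisons became 0 with an estimated correlation, 21 by fry, 81 with the block, 98 without both control male replicate 2 libraries and 95 without cKO replicates 4 and 5. With each library left out in turn 33 of the 78 were kept, and 45 were lost or turned with at least 1.

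Leaving out 1 library at a time gave 9 to 30 genes in female mesometrial, 20 to 182 in male mesometrial, 5 to 42 in female anti-mesometrial and 39 to 368 in male anti-mesometrial decidua. For the difference between compartments it gave 0 to 131. That count was 131 without control male anti-mesometrial replicate 2, 12 without control male mesometrial replicate 2, 19 without control female anti-mesometrial replicate 5, and 7, 8 and 11 without cKO male mesometrial 1 and anti-mesometrial 2 and 3. It was 0 without control female mesometrial 1, 3 or 4, control male mesometrial 1 or 5, cKO female mesometrial 1, 2, 3 or 5, cKO male mesometrial 2, 3 or 4, control female anti-mesometrial 1 or 2, control male anti-mesometrial 1, 3 or 4, or anti-mesometrial cKO 4 or 5 of either sex. It was 2 without control female mesometrial 5, control female anti-mesometrial 3 or 4 or control male anti-mesometrial 5, 4 without cKO female anti-mesometrial 3 and 5 without control male mesometrial 4. Male against female stayed at 0 except without control male mesometrial replicate 3 (1) and cKO male mesometrial replicate 4 (1). With 1 library left out, 5596 named gene values kept their side of the threshold, 345 lost and 19 gained a call. Some signs turned.

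The Y-linked difference was 3.35, 2.38, 6.94 and 6.79 CPM in control mesometrial, control anti-mesometrial, cKO mesometrial and cKO anti-mesometrial decidua, 2.89, 2.69, 6.20 and 7.41 CPM with TMM-scaled sizes, and 2.69 to 3.83, 1.67 to 2.86, 4.44 to 8.62 and 4.63 to 8.32 CPM with 1 library left out. The 2-sided exact permutation p, the smaller tail doubled as for the full groups, was then 0.0159 in each case. A first calculation by absolute difference, replaced after its values were seen, gave without 1 female-labelled library 0.0556 in control anti-mesometrial and cKO mesometrial and 0.0635 in cKO anti-mesometrial decidua, past no threshold of 0.05.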

Other observations

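In this part the lists and their tests were planned, and the tests without both control male replicate 2 libraries, without cKO replicates 4 and 5 and without single libraries, like the choice of lists to describe, came after the results were seen. Macrophage and dendritic cell genes lay higher in mesometrial control decidua, with 12 of 18 up and 2 down (median log2 fold change 0.81, camera adjusted p = 0.0303; adjusted p = 0.782 with an estimated correlation). Mrc1, the mannose receptor gene, stood at 10.1 ± 1.58 against 3.84 ± 3.16 CPM and the integrin gene Itgax at 4.14 ± 0.996 against 1.40 ± 1.17 CPM, whereas Csf1r, the receptor gene for colony-stimulating factor 1, which decidual cells can also carry, was lower at 47.3 ± 23.4 against 151 ± 54.3 CPM (mean ± SD, mesometrial first, n = 10). Of 21 complement and coagulation genes 13 rose and 4 fell mesometrially (median 0.76, camera adjusted p = 0.0334; adjusted p = 0.599 with an estimated correlation), with the complement regulator gene Cd55 at 212 ± 35.7 against 50.4 ± 62.4 CPM and the protein S gene Pros1 at 231 ± 53.0 against 65.1 ± 80.7 CPM, but the coagulation inhibitor gene Tfpi2 at 13.9 ± 14.3 against 95.4 ± 33.6 CPM. Of 26 DNA replication genes 19 rose and 2 fell (median 0.45, camera adjusted p = 0.0334; adjusted p = 0.782 with an estimated correlation). The cyclin gene Ccnd3 stood at 142 ± 20.04 against 66.7 ± 32.3 CPM and the helicase gene Mcm6 at 75.3 ± 10.8 against 43.1 ± 12.2 CPM, whereas the ribonucleotide reductase gene Rrm2 fell (2957 ± 692 against 6282 ± 1225 CPM). Angiogenic factors went both ways, 9 of 19 up and 5 down (camera adjusted p = 0.427), with pleiotrophin, Ptn, at 1454 ± 236 against 503 ± 413 CPM, neuropilin 1, Nrp1, at 103 ± 20.6 against 31.2 ± 27.1 CPM and Fgf2 at 42.8 ± 20.9 against 143 ± 40.8 CPM. Adjusted over the list alone, the counts were the same for each of these 4 lists. The DNA replication call was lost without both control male replicate 2 libraries (camera adjusted p = 0.092), without the anti-mesometrial one alone (0.0734) and without control female anti-mesometrial replicate 5 (0.0590), and the macrophage and complement calls were lost without cKO replicates 4 and 5 (camera adjusted p = 0.0517 and 0.0667). Without control male anti-mesometrial replicate 2 the anti-mesometrial means of Cd55 and Pros1 were 30.9 and 39.8 CPM.

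In cKO against control, DNA replication genes lay higher in female anti-mesometrial decidua (median 0.23, 21 of 26 positive, camera adjusted p = 9.94e-04), and ER folding genes lay lower there (median -0.17, 2 of 20 positive, camera adjusted p = 0.00726). For both, 0 members passed over all genes or adjusted over the list alone, adjusted p = 0.558 with an estimated correlation, and the calls were lost without cKO replicates 4 and 5 (camera adjusted p = 0.495 and 0.0594). The DNA replication call was also lost without control 5 (0.0628), and the ER folding median was -0.11 without cKO 5. In male anti-mesometrial decidua glycolysis and hypoxia genes lay lower (median -0.33, 4 of 23 positive, camera adjusted p = 6.48e-04), with 1 member fallen over all genes and over the list alone, the phosphoglycerate mutase gene Pgam1 (104 ± 1.69 against 132 ± 10.97 CPM). Basement membrane genes lay lower in male mesometrial (median -0.17, camera adjusted p = 0.0489, 3 of 16 lower adjusted over the list alone) and male anti-mesometrial decidua (median -0.28, camera adjusted p = 0.0292, 0 lower). With an estimated correlation these lists had adjusted p = 0.844 in the mesometrial and 0.721 in the anti-mesometrial part. The glycolysis and basement membrane calls of male anti-mesometrial decidua were lost without control male anti-mesometrial replicate 2 (camera adjusted p = 0.534 and 0.289). The latter was also lost without cKO 1 (0.235) or 3 (0.194), and the mesometrial basement membrane call without control 1, 3, 4 or 5 or cKO 1 or 3 (0.0617 to 0.135). Genes of LIF and STAT3 signalling passed in no stratum (camera adjusted p from 0.521 to 0.965), with the LIF receptor gene Lifr at 102 ± 21.0 against 53.5 ± 6.49 CPM in female and 117 ± 59.6 against 73.2 ± 23.6 CPM in male anti-mesometrial decidua, neither past the threshold. Steroid receptor genes, matrix proteases, immediate early genes, lymphocytes, neutrophils, embryonic erythroid, yolk sac and embryo genes passed as lists in no cKO comparison (camera adjusted p from 0.1004 to 0.9595). The epidermal growth factor family gene Ereg, of the decidualization regulators, rose in male anti-mesometrial decidua (2.67 ± 0.702 against 0.852 ± 0.523 CPM, adjusted p = 0.0401). Without cKO replicates 4 and 5 the calls of Pgam1 and Ereg were lost (adjusted p = 0.0856 and 0.122), as they were without 7 and 6 of 10 single libraries.

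Between male and female conceptuses, further lists passed camera without passing with an estimated correlation. In control mesometrial decidua endothelial genes lay higher with male conceptuses (median 0.22, 16 of 20 positive, camera adjusted p = 0.00122; adjusted p = 0.701 with an estimated correlation; median 0.14 without control female replicate 5). In control anti-mesometrial decidua glycolysis (median 0.53, 23 of 23 positive), interferon-response (0.78, 23 of 24) and collagen genes (1.28, 17 of 19) lay higher and prolactin-family genes lower (-0.56, 0 of 4; adjusted p = 0.549 with an estimated correlation for each). In the fit without both control male replicate 2 libraries, or without the anti-mesometrial one alone, the collagen and prolactin calls were lost (camera adjusted p = 0.531 and 0.102) and those of glycolysis and interferon genes were not (3.55e-04 and 0.0433), with medians of 0.10 and 0.08. In cKO anti-mesometrial decidua natural killer cell genes lay higher with male conceptuses (median 1.57, 15 of 17 positive, camera adjusted p = 1.83e-04; adjusted p = 0.628 with an estimated correlation), which was lost without cKO replicates 4 and 5 (0.0871) and without cKO female replicate 5 alone (0.0631). The male replicates 1 and 2 had 238 and 259 CPM of these genes, against 84.8 to 110 CPM in the other 3 male and 61.9 to 128 CPM in the female libraries, and replicate 2 also stood apart in compartment position (0.225). Without male replicate 2 the median was 1.06. No member of these lists passed over all genes or adjusted over the list alone.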
